A study of Arabidopsis thaliana with 8 samples.

How the data were processed

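The data are poly(A) RNA sequencing of Arabidopsis thaliana Col-0 leaf protoplasts. Per the labels' protocols, leaves of 4-week-old plants were digested for 90 min, cells were transfected with plasmid DNA by polyethylene glycol, incubated overnight, and libraries were made with a NEBNext Ultra II RNA kit, which does not mark strand. The sample titles put 4 libraries in div1 and 4 in ev. No label states that replicates came from separate plants or transfections, so p-values measure the spread between these samples, which may be technical. Chemical induction, translation inhibitors and cell sorting are not given in the sources used here.

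Per the submitters' processing notes, the tools were fastp 0.21.0, HISAT2, featureCounts 2.0.1 and DESeq2, with the TAIR10 build. Settings, filters and strand options are not given in the sources used here. The only table used here is the authors' deposited comparison. Per the file headers it gives for each gene a mean normalized count over all libraries (a signal averaged by the authors), a log2 fold change and its standard error, a score (the test statistic), a p-value and an adjusted p-value. The deposited log2 fold change divided by its standard error equals the deposited score to within 9.06e-14. The table holds 2958 genes, its largest adjusted p is 0.0499, and its means run from 20.4 to 203901 with a median of 1092. Values per library were not used here, so depth per library is unknown and precision is known only through the authors' standard errors, whose median is 0.189 on the log2 scale. No test of samples was run; the authors' calls at an adjusted p under 0.05 were read as deposited, as the plan provided for a table of this kind.

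The number of genes behind the adjustment was recovered as adjusted p times rank divided by p, whose largest value was 18010, also reached at the last rank. In 2548 genes the value lay within 0.5 of it. On simulated data the largest value was 15000 for 15000 genes, and the value at the last rank was 14639 when 5 called genes were removed. Group means were estimated from the overall mean and the fold change, taking both groups at 4 libraries. An estimated mean under 0.75, which is 3 counts over 4 libraries, was taken as the floor, and a fitted fold against it is not read as a size. Direction was read from DIV1, since the table does not name the numerator.

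Gene names, descriptions, coordinates and upstream sequence came from the TAIR10.1 reference annotation, to which 2957 identifiers matched and 1 did not. Of the called genes 2920 were protein-coding and 799 overlapped another annotated gene.

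Before the data were examined, 20 gene lists with 356 genes, 24 description keywords, the rule for named genes, the motif test and the alternatives were fixed. Named are the DIV and RADIALIS family, the 12 highest and 12 lowest fold changes with a mean of at least 50, up to 4 members per list and up to 3 per family by adjusted p, and the 10 smallest adjusted p. Each list or family was tested by a two-sided Fisher's exact test of its higher and lower calls against those of all other called genes, with Benjamini-Hochberg adjustment over the lists, or families, with a call. In simulations 4.1% of 1000 random lists of 20 calls passed at p under 0.05. Lists with 18 higher and 2 lower calls passed in 100%, which their counts alone fix, so this measures no power. Each gene list here held fewer than 20 calls. Counts adjusted over the list alone could be bounded from below only, and in each list at least as many members passed so as were called. In the keyword families the bound fell below the calls for ribosomal protein (22), ubiquitin (18), F-box (6), pectin (18), MYB (26) and zinc finger (61) genes. Added after the data were seen was a one-sided hypergeometric test against the 18010 tested genes with each member taken as tested. It overstates p where members were untested (1.5% of random lists of independent genes passed). It also treats genes as independent, so p may be too small where members change together or share reads. Further additions were a scan of 2375 words and word pairs of the descriptions in both directions, a scan of 2080 words of 6 bases, and lists of pollen, seed and peroxisomal genes. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, with matplotlib 3.10.9 for plots. Intervals are at 95%, by the Wilson method for shares.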

Results

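DIV1 is an Arabidopsis transcription factor with MYB-type DNA-binding domains, of the DIVARICATA group. The series asked which genes respond when DIV1 is introduced into leaf cells by TARGET, an assay in which protoplasts receive a plasmid encoding a transcription factor and their transcripts are then sequenced. Protoplasts, which are leaf cells freed of their walls by enzyme, came from rosette leaves of 4-week-old Col-0 plants and took up plasmid with polyethylene glycol. Poly(A) RNA was sequenced from 8 libraries, 4 labelled div1 and 4 labelled ev. The labels do not expand ev, which in this kind of assay commonly stands for the empty vector. Values come from 1 results table of the authors, which lists the 2958 genes they called at an adjusted p under 0.05 and holds means over all libraries, with no values per library. The total count of each library is therefore unknown, and neither the spread between replicates nor a left-out library could be looked at directly.

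The introduced gene itself was among the strongest changes. DIV1 (AT5G58900, chromosome 5, 23783102 to 23785512, minus strand, TAIR10.1) had a log2 fold change of 7.61 (SE 0.88, adjusted p 1.12e-15) and a mean normalized count of 45281 in the authors' deposited table. The table does not name which group is the numerator, and this value sets the direction used throughout, with positive values read as higher in the div1 libraries. Reads from an introduced copy and from the chromosomal gene carry the same identifier. Its standard error was the largest among the 221 called genes with a mean of at least 10000. Of the 15 members of the DIV and RADIALIS family examined, 4 were called higher, 0 lower, and 11 were not called. The relatives were DIV2, MYBS2 and KUA1, with log2 fold changes of 0.64 (SE 0.13), 0.56 (SE 0.17) and 1.86 (SE 0.35) in the authors' deposited table. Both DIV2 and MYBS2 overlap annotated genes on the opposite strand, and the library kit does not keep strand.

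Of 18010 genes tested, a number recovered from the deposited p-values, 16.4% were called, 1646 higher and 1312 lower in the div1 libraries. A change of 2-fold or more was listed for 625 higher and 397 lower genes, and one of 4-fold or more for 206 higher and 61 lower genes. The largest increases with a mean count of at least 50 were, DIV1 aside, in genes with low estimated means in the ev libraries. CRU2, a seed storage globulin, and PGA4, a polygalacturonase, had estimated ev means under the floor of 3 counts over 4 libraries, so their fitted folds in the authors' deposited table give no size. Better supported were PUP1, a purine and cytokinin permease, at 6.68 (SE 0.56), SVL2 at 5.81 (SE 0.35) and AT4G12980, annotated as auxin-responsive, at 5.58 (SE 0.46), as log2 fold changes in the authors' deposited table. The sugar transporters STP2 and STP14 had log2 fold changes of 6.41 (SE 0.95) and 5.50 (SE 1.33), and CYP706A7 one of 6.04 (SE 0.87), in the authors' deposited table. The remaining genes of the 12 highest, namely AT2G28680, sks13 and AT2G33160, had log2 fold changes of 6.69 (SE 1.21), 5.95 (SE 1.71) and 5.66 (SE 1.24) in the authors' deposited table. The standard errors of several of these genes exceed 1, so their sizes are loosely fixed, and PGA4, STP2, sks13 and AT2G33160 are transcripts known from pollen.

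**Figure D1:**
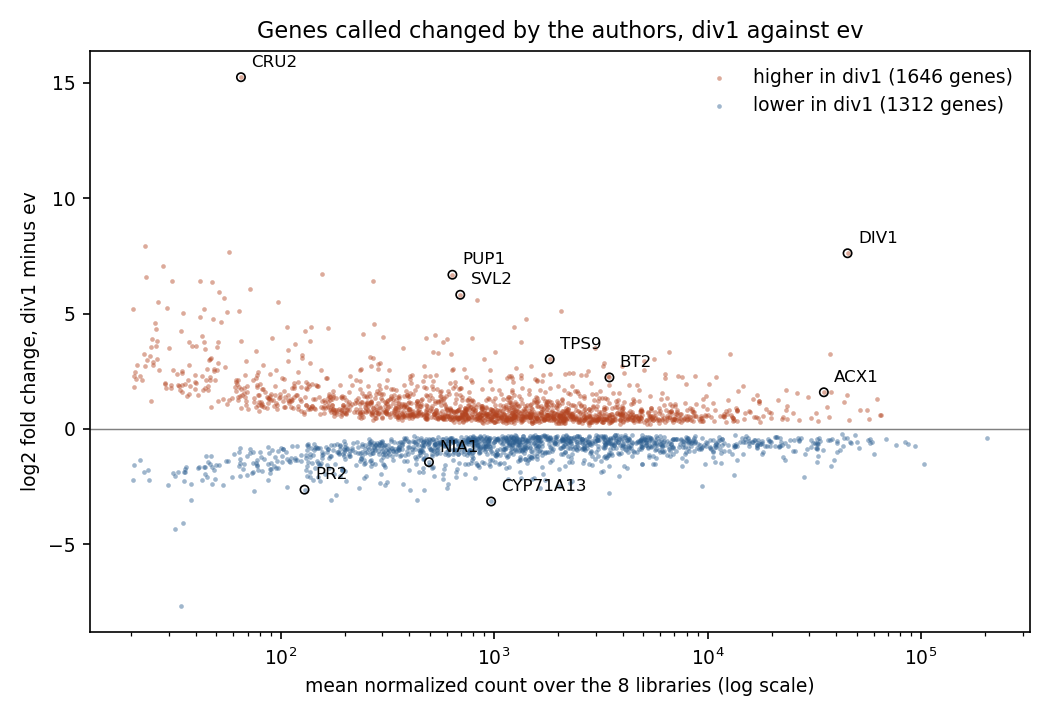
Log2 fold change of div1 minus ev (y axis) against the mean normalized count over all libraries (x axis, log scale), each point being a gene the authors called, with 1646 higher genes in orange and 1312 lower genes in blue. DIV1 stands alone at high counts with a log2 fold change of 7.61, the point of CRU2 is a fitted value against an ev mean under the floor, and most other large increases lie among genes with low means.

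Among genes with a mean count of at least 50, the largest decreases were smaller than the largest increases. The lowest log2 fold changes at such means in the authors' deposited table were those of CYP71A13, a cytochrome P450 of camalexin synthesis, at -3.14 (SE 0.32), AT5G02580 at -3.10 (SE 0.52) and BGLU18, which releases abscisic acid from its glucose ester, at -3.09 (SE 0.89). BSMT1, which makes methyl salicylate, CKX5, a cytokinin-degrading oxidase, and AT3G22275, annotated as a jasmonate ZIM-domain protein, stood at -2.87 (SE 0.96), -2.80 (SE 0.40) and -2.64 (SE 0.40) in the authors' deposited table. Next came the pathogenesis-related glucanase PR2 at -2.63 (SE 0.50), the TIR-domain gene AT1G52900 at -2.58 (SE 0.29), and AT2G37440 and EXL3 at -2.57 (SE 0.28) and -2.54 (SE 0.35) in the authors' deposited table. The cysteine proteinase gene AT2G34080 and AT4G35165 had log2 fold changes of -2.68 (SE 0.56) and -2.65 (SE 0.58) in the authors' deposited table. CYP71A13, BSMT1, CKX5, AT2G34080 and AT3G22275 overlap other annotated genes, as do 27.0% of all calls, so part of their counts may belong to a neighbour. At a lower mean count of 34.3, AT4G18630 had a log2 fold change of -7.67 (adjusted p 1.49e-07) in the authors' deposited table, a fitted value against an estimated div1 mean under the floor, and it is named after its value was seen.

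The 10 genes with the smallest adjusted p were all higher in the div1 libraries. The smallest adjusted p in the authors' deposited table, 6.44e-70, belonged to ACX1 (AT4G16760, chromosome 4, 9424534 to 9428895, minus strand, TAIR10.1), an acyl-CoA oxidase of peroxisomal fatty acid breakdown, with a log2 fold change of 1.59 (SE 0.09). It was followed by the kelch-repeat F-box gene AT1G23390 at 2.84 (SE 0.16) and TPS9, of the trehalose phosphate synthase family, at 3.02 (SE 0.17), as log2 fold changes in the authors' deposited table. SVL2, NRAMP1, a manganese and iron transporter, and ZF14, annotated as a MATE efflux protein, came next, with adjusted p of 4.33e-59 for NRAMP1 and a log2 fold change of 3.33 (SE 0.20) for ZF14 in the authors' deposited table. PATL1, SQE6, NAC001 and AT2G46550 completed the 10 smallest, at 2.71 (SE 0.17), 3.26 (SE 0.20), 2.22 (SE 0.14) and 2.17 (SE 0.14) in the authors' deposited table. NRAMP1 overlaps a gene on the opposite strand.

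Genes of nitrogen use were called in both directions. Of the 24 members of the list of nitrate uptake and reduction, 4 were higher, 4 lower and 16 not called. Nitrate reductase NIA1 and nitrite reductase NIR1 had log2 fold changes of -1.44 (SE 0.25) and -0.62 (SE 0.16), while the nitrate transporter gene NRT2.6 and the glucose-6-phosphate dehydrogenase gene G6PD2 rose by 3.02 (SE 0.79) and 0.96 (SE 0.21) in the authors' deposited table. The other nitrate reductase, NIA2, which was named only after its value was seen, had a log2 fold change of -0.67 (SE 0.18) in the authors' deposited table. In the list of ammonium assimilation and amino acid synthesis, of 23 members, 6 were higher, 0 lower and 17 not called. These included the cytosolic glutamine synthetases GLN1;1 at 0.82 (SE 0.09, adjusted p 5.6e-18) and GLN1;4 at 1.46 (SE 0.30), and the glutamate synthases GLU1 at 1.07 (SE 0.17) and GLT1 at 0.79 (SE 0.14), as log2 fold changes in the authors' deposited table. Among 26 regulators of the nitrogen response, 4 were higher, 4 lower and 18 not called. BT2, a BTB and TAZ domain protein that limits nitrogen use efficiency, rose by 2.23 (SE 0.25) and the Dof factor CDF1 by 0.62 (SE 0.17), and the cytokinin response factor CRF4 and the NIN-like protein NLP4 stood at -1.53 (SE 0.30) and -0.52 (SE 0.13), on the log2 scale in the authors' deposited table. The direction of the 6 ammonium assimilation calls differed from that of all other calls before adjustment only (Fisher's exact test, two-sided, p = 0.0371, adjusted p = 0.209 over 17 lists). GLU1, GLT1, CRF4 and NLP4 overlap annotated neighbours.

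In the lists of immunity, most calls were lower, and most members were not called. In the salicylic acid list of 20 members, 8 were lower, 1 was higher and 11 were not called. PBS3 and EDS5, which act in salicylic acid synthesis and export, and PR2 had log2 fold changes of -1.52 (SE 0.16), -1.20 (SE 0.24) and -2.63 (SE 0.50), whereas the salicylic acid receptor gene NPR1 stood at 0.68 (SE 0.13) in the authors' deposited table. In the list of pattern-triggered immunity, of 18 members, 6 were lower, 1 higher and 11 not called. The camalexin pathway genes CYP71A13, PAD3 and CYP79B2 fell, with log2 fold changes of -3.14 (SE 0.32), -2.07 (SE 0.23) and -1.62 (SE 0.19), and WRKY40 stood at -0.62 (SE 0.17), in the authors' deposited table. Against the direction of all other calls, the salicylic acid split gave p = 0.0132 (adjusted p = 0.112) and the pattern-triggered split p = 0.0493 (adjusted p = 0.209) in Fisher's exact test, so neither passed after adjustment over 17 lists. An enrichment test was added after the data were seen, taking each member as tested and genes as independent. It gave adjusted p = 0.00177 for lower calls in the salicylic acid list and adjusted p = 0.0171 in the pattern-triggered list. EDS5, NPR1 and WRKY40 overlap genes on the opposite strand.

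**Figure D2:**
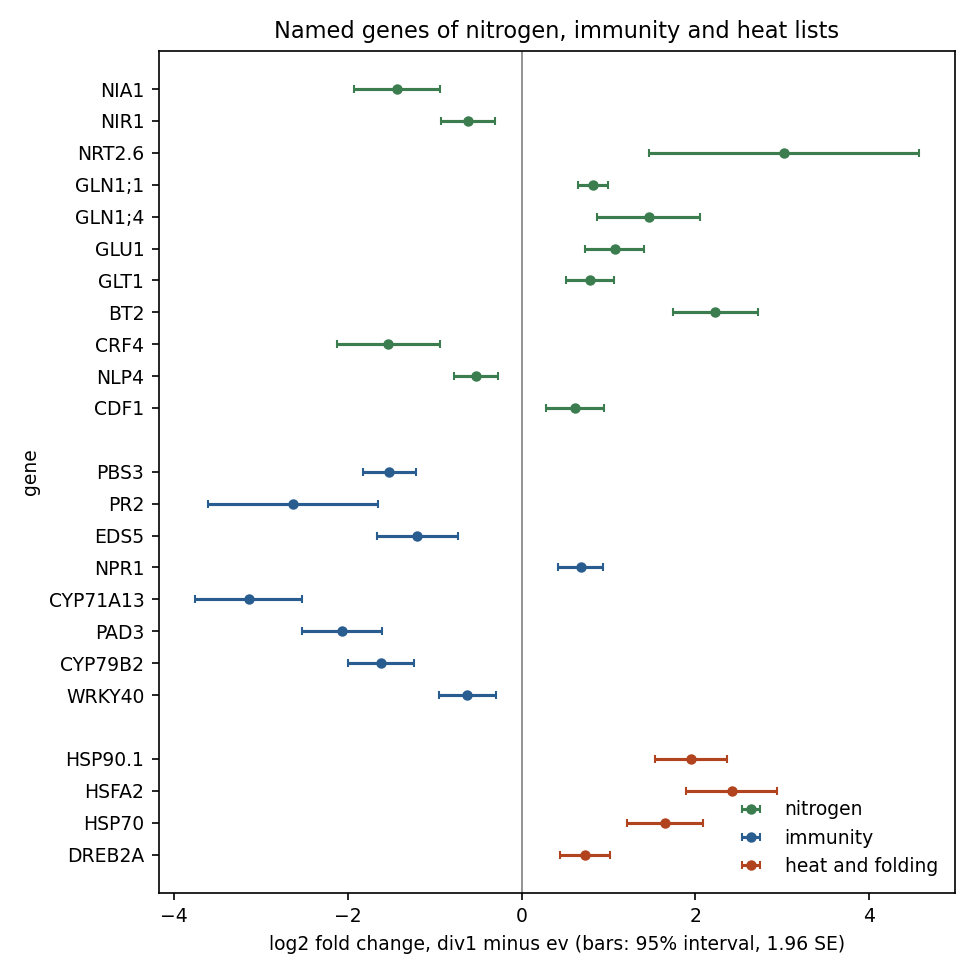
Log2 fold change of div1 minus ev (x axis) for the named genes of the nitrogen, immunity and heat lists (y axis), with bars for the 95% interval made from the standard errors in the authors' deposited table. Ammonium assimilation and heat genes lie to the right of 0, and the immunity genes other than NPR1 lie to the left.

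In the list of heat response and protein folding, 8 of 18 members were called higher, 0 lower and 10 not called. The higher members included the chaperone genes HSP90.1 at 1.95 (SE 0.21) and HSP70 at 1.65 (SE 0.22), the heat shock factor HSFA2 at 2.42 (SE 0.27) and DREB2A at 0.73 (SE 0.15), as log2 fold changes in the authors' deposited table. The split test gave p = 0.0106 (Fisher's exact test, adjusted p = 0.112 over 17 lists), and the added enrichment test an adjusted p of 0.00181. DREB2A overlaps a gene on the opposite strand. In total 4 lists had an unadjusted split p under 0.05 and 0 of 17 had an adjusted one, by Fisher's exact test.

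Of the families read from the annotation, 6 of 24 passed Fisher's exact test after adjustment. Among 344 genes with ribosomal protein in the description, 34 were higher and 3 lower (Fisher's exact test, adjusted p = 5.46e-05). With every member taken as tested, 31.4 higher and 25.1 lower calls would be expected. AT2G28815, AT1G25260 and the elongation factor gene LOS1 had log2 fold changes of 2.11 (SE 0.23), 0.67 (SE 0.14) and 0.42 (SE 0.10) in the authors' deposited table. The 111 heat shock genes had 23 higher and 1 lower call (adjusted p = 2.3e-04). Histone-annotated genes, 115 in number, had 29 higher and 3 lower calls (adjusted p = 2.3e-04), led by HIS4, with AT1G09200 and AT3G53730 at 1.62 (SE 0.22) and 1.19 (SE 0.16) on the log2 scale in the authors' deposited table. Receptor-like genes went the other way, with 7 higher and 27 lower calls among 148 genes (adjusted p = 2.3e-04), and the kinases CRK7, CRK8 and EMB1290 at -2.18 (SE 0.23), -2.05 (SE 0.25) and -0.64 (SE 0.10) on the log2 scale in the authors' deposited table. WRKY factors had 3 higher and 12 lower calls among 72 genes (adjusted p = 0.0292), with WRKY17 and WRKY57 at -0.83 (SE 0.16) and -0.91 (SE 0.20) but WRKY75 at 0.54 (SE 0.12) on the log2 scale in the authors' deposited table. Ubiquitin-annotated genes had 22 higher and 5 lower calls among 361 (adjusted p = 0.0292), among them SIS at 3.51 (SE 0.30), AT2G22890 at 2.28 (SE 0.23) and the autophagy receptor NBR1 at 0.74 (SE 0.10) on the log2 scale in the authors' deposited table. None of these 6 splits passed among calls of at least 2-fold, and among calls with an adjusted p under 0.01 those of the ribosomal protein (adjusted p = 0.0742), WRKY and ubiquitin (both adjusted p = 0.0539) genes did not pass. In the added enrichment test the histone (adjusted p = 1.58e-05) and heat shock (adjusted p = 0.00239) higher calls and the receptor-like lower calls (adjusted p = 1.92e-04) passed, the histone one being lost among calls of at least 2-fold (adjusted p = 0.466). The ribosomal protein and ubiquitin higher calls (both adjusted p = 1) and the WRKY lower calls (adjusted p = 0.0663) did not pass it. Near-identical histone, chaperone and receptor copies may share reads, so single members are uncertain, and SIS, NBR1 and EMB1290 overlap neighbours.

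The other families did not pass, yet held some large changes. The cytochrome P450 genes CYP71B24 and CYP71B2 had log2 fold changes of 2.37 (SE 0.17) and 3.98 (SE 0.34), with 19 higher and 15 lower calls in the family of 248, in the authors' deposited table. The glutathione transferase genes GSTU5 and GSTF8 stood at 1.54 (SE 0.15) and 1.63 (SE 0.17), and GSTU12 at -0.82 (SE 0.11), as log2 fold changes in the authors' deposited table. Among MYB genes MYB6 and MYB7 were higher at 2.83 (SE 0.32) and 1.79 (SE 0.22), and MYB2 lower at -1.08 (SE 0.10), on the log2 scale in the authors' deposited table. The thioredoxin-dependent peroxidase genes TPX2 and TPX1 had log2 fold changes of 3.51 (SE 0.27) and 1.18 (SE 0.15) in the authors' deposited table. Expansins EXPA4 and EXPA1, which loosen cell walls, stood at -1.47 (SE 0.34) and -1.08 (SE 0.29) on the log2 scale in the authors' deposited table.

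None of the hormone, clock, senescence and photosynthesis lists passed the split test. Few calls limit this test. Ethylene and photosynthesis had all their calls on the same side, yet gave p = 0.0872 and p = 0.134 before adjustment (Fisher's exact test). Not passing therefore does not show a lack of direction in such short lists. In the abscisic acid list of 24 members, 5 were higher and 2 lower, the latter being the phosphatases HAI1 and ABI2, which restrain abscisic acid signalling, at -1.35 (SE 0.21) and -1.12 (SE 0.22), against ABF4 at 1.09 (SE 0.21) and RD22 at 1.27 (SE 0.25), on the log2 scale in the authors' deposited table. Of 20 jasmonate genes 4 were higher and 3 lower, with the repressor gene JAZ5 at -0.99 (SE 0.11), JAZ7 at 1.18 (SE 0.28), and the synthesis genes AOC1 and AOC2 at 0.52 (SE 0.15) and 0.50 (SE 0.15), on the log2 scale in the authors' deposited table. Of 12 cytokinin genes 3 were higher and 2 lower, with the response regulators ARR4, ARR8 and ARR9 at 1.44 (SE 0.24), 1.87 (SE 0.34) and 1.87 (SE 0.33) and the degrading oxidase CKX5 at -2.80 (SE 0.40), on the log2 scale in the authors' deposited table. Ethylene had 0 higher and 3 lower calls among 8 genes, the synthase genes ACS6 and ACS2 at -1.07 (SE 0.18) and -0.77 (SE 0.16) and EBF2 at -0.41 (SE 0.13), on the log2 scale in the authors' deposited table. Single calls were made in the auxin list of 7, IAA19 at -1.63 (SE 0.56), and in the flavonoid list of 16, the anthocyanin regulator PAP1 at -1.76 (SE 0.29), on the log2 scale in the authors' deposited table. Of 19 clock genes 4 were higher and 4 lower, with RVE2 and RVE1 at 2.34 (SE 0.29) and 1.19 (SE 0.26) and LHY and RVE8 at -0.82 (SE 0.17) and -0.63 (SE 0.16), on the log2 scale in the authors' deposited table. Of 19 starvation and senescence genes 4 were higher and 1 lower, with NAP at 0.86 (SE 0.15), ORE1 at 0.87 (SE 0.17), DIN10 at 1.19 (SE 0.24) and SAG13 at -1.18 (SE 0.22), on the log2 scale in the authors' deposited table. Photosynthesis had 4 higher and 0 lower calls among 48 genes, PSBO2, LHCB4.1, LHCA4 and PSAD1, at 1.78 (SE 0.41), 0.59 (SE 0.15), 1.00 (SE 0.25) and 0.91 (SE 0.25), on the log2 scale in the authors' deposited table. ABF4, ARR8, ARR9, CKX5, EBF2, RVE1, DIN10 and LHCA4 overlap neighbours.

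**Figure D3:**
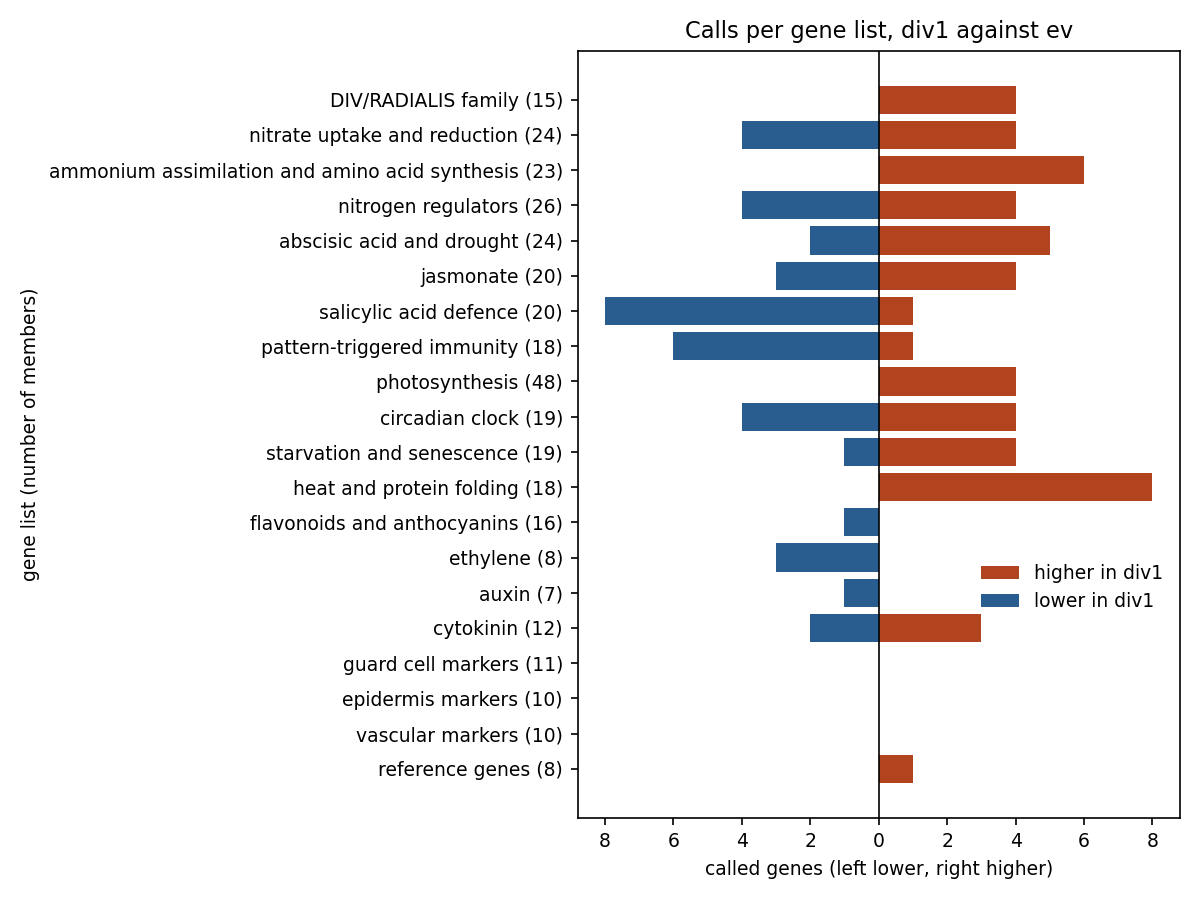
Number of called genes (x axis) in each of 20 gene lists (y axis, with the number of members), lower in div1 to the left and higher to the right. Salicylic acid defence reaches 8 lower calls, heat and protein folding 8 higher calls, and the 3 marker lists of guard cells, epidermis and vasculature hold none.

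Markers of other leaf cell types gave no call, with 0 of 11 guard cell, 0 of 10 epidermis and 0 of 10 vascular genes in the authors' deposited table. Such members may have been untested or below the threshold, which a table of called genes cannot separate. Of 8 reference genes, UBQ10 was called, at 0.34 (SE 0.10) on the log2 scale in the authors' deposited table. A single organelle-encoded transcript, ATMG01380, was called, at -0.84 (SE 0.29) in the authors' deposited table.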

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

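Enrichment tests and the adjusted p under 0.01 for lists and families were chosen after the data were seen. The count of 2958 changed genes was 1257 at an adjusted p under 0.001, 1022 at an absolute log2 fold change of at least 1 and 824 by Bonferroni over the tested genes. Higher genes numbered 759, 625 and 529 and lower genes 498, 397 and 295 in those settings, and 822 lower genes had an adjusted p under 0.01. Fewer genes can pass a stricter limit by construction. The share of higher calls moved from 55.6% to between 55.0% and 64.2%. Of the 6 families with a one-sided split, 3 (heat shock, histone and receptor-like) passed among calls with an adjusted p under 0.01 and 0 among calls with an absolute log2 fold change of at least 1; the cause was not tested. No gene list passed the split test under any setting run, and lists with few calls had little room to pass. Requiring a mean of at least 50 left 47 tests of single lists and families on their side of the threshold; an adjusted p under 0.01 left 43 and weakened 3, and the 2-fold limit left 36 and weakened 7. The DIV1 fold change cannot move under these settings, as they only select genes. No paired analysis was possible because the table used here holds no values per library. For the same reason other normalizations, another count tool, no low-count filter, a pseudocount, left-out replicates, rank or rotation tests of lists and other splits of the samples were not run. Depth per library is unknown, so it cannot be said which uncalled genes were too shallow to test.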

Other observations

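The word scan, the enrichment tests, the marker lists, the grouping of proteasome, ribosomal protein and receptor genes, the comparison by distance from the gene start and the reading over the median of base orders were chosen after the data were seen, while both motif tests were planned. Among the 2375 words and word pairs, 11 passed the enrichment test for higher calls and 21 for lower calls after adjustment. These words share genes and are not separate findings. The 11 all name proteasome, histone or heat shock genes, and many of the 21 restate the same receptor, kinase and disease resistance genes. Of 45 genes described with the word proteasome, 23 were called higher, 0 lower and 22 were not called, with log2 fold changes of the calls between 0.38 and 0.80, such as RPT5B at 0.80 (SE 0.12), PBD2 at 0.64 (SE 0.10) and PAA2 at 0.56 (SE 0.08) in the authors' deposited table (adjusted p = 1.47e-09). Of 11 genes described by the words regulatory particle, which name proteasome subunits too, 7 were higher and 1, RPN12b at -0.86 (SE 0.21), was lower in the authors' deposited table. Genes of the annotated histone superfamily had 22 higher and 1 lower call among 34, with 11 not called and a median log2 fold change of 0.83 over the called genes (adjusted p = 1.07e-11), among them AT1G09200 at 1.62 (SE 0.22) and the centromeric histone gene HTR12 at 0.93 (SE 0.29) in the authors' deposited table. Chaperone genes annotated as shock proteins had 15 higher and 0 lower calls among 45, with the cytosolic HSP81-2 at 1.68 (SE 0.26) and the endoplasmic reticulum chaperones BIP1 and BIP2 at 0.62 (SE 0.13) and 0.57 (SE 0.14) in the authors' deposited table.

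Lower calls gathered in receptor families of the cell surface and in intracellular immune receptors. Receptor-like proteins had 17 lower and 1 higher call among 52 (adjusted p = 7.44e-05), among them RLP43 at -1.58 (SE 0.18) and RLP53 at -1.51 (SE 0.18), with RLP19 at 0.65 (SE 0.14), on the log2 scale in the authors' deposited table. Cysteine-rich receptor kinases had 13 lower and 2 higher calls among 35 (adjusted p = 2.95e-04), CRK7 and CRK6 at -2.18 (SE 0.23) and -2.26 (SE 0.41) and CRK42 at 1.93 (SE 0.40), in the authors' deposited table. Among 91 TIR-NBS-LRR genes 21 were lower and 5 higher (adjusted p = 7.5e-04), RPS6 and RPS4 at -0.66 (SE 0.12) and -0.33 (SE 0.11) against SNC1 at 0.70 (SE 0.13), in the authors' deposited table. These genes lie in clusters of similar copies, and reads shared between copies were not examined. The S-locus lectin kinases had 8 lower and 0 higher calls among 21, most of them with neighbouring identifiers on chromosome 1. Of 13 genes described with the word cytokinin, 0 were higher and 6 lower (adjusted p = 0.0266), namely the oxidases CKX3, CKX4, CKX5 and CKX7 and the response factors CRF3 and CRF4, with CRF3 at -2.37 (SE 0.32) and CKX3 at -1.91 (SE 0.43) in the authors' deposited table, whereas the higher regulators ARR4, ARR8 and ARR9 do not carry that word. The adjusted p given for these words are from the enrichment test. In Fisher's exact test of the split, receptor-like proteins (adjusted p = 0.00275) and TIR-NBS-LRR genes (adjusted p = 0.0212) passed. Cysteine-rich receptor kinases (adjusted p = 0.0645), S-locus lectin kinases (adjusted p = 0.0787) and the word cytokinin (adjusted p = 0.307) did not. RPT5B, PBD2, RLP53 and CRK42 overlap genes on the opposite strand.

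DIVARICATA-type proteins are known to bind I-box-like elements, and the planned test asked whether GATAAG lay more often upstream of higher than of lower genes. Within 500 bp, 29.6% of 1646 higher genes (27.5 to 31.9%) and 17.5% of 1311 lower genes (15.6 to 19.7%) carried it, against 22.4% of 27444 coding genes, an odds ratio of 1.98 (1.66 to 2.36, Fisher's exact p = 1.7e-14), and TATCCA gave 1.63 (1.38 to 1.93, p = 8.77e-09). The test of base composition set in advance asked that GATAAG exceed all 59 other orders of its bases. It failed, because GGATAA reached 2.06, so by that criterion composition is not excluded. GGATAA shares GATAA with GATAAG and, on the other strand, TATCC with TATCCA. Its odds ratio therefore cannot separate composition from the tested motifs. A reading chosen afterwards points the other way, the other orders having a median of 1.003 and a 95th percentile of 1.24, below the lower bound of 1.66. The odds ratio was 2.71 in the nearest 200 bp and between 1.43 and 1.71 in the other 200 bp bins to 1000 bp, so that the nearest bin exceeded the upper 95% bound of the farthest, as an element close to the start predicts, although their intervals overlap and the other bins show no steady decline. Of 2080 words of 6 bases, GGATAA, AGATAA, GATAAG and TATCCA had the 4 smallest p. These words overlap and are not separate findings. The next by p, GATAAT, AAGATA and AGGATA, had odds ratios of 1.54, 1.51 and 1.61. All these words contain GATA on 1 strand, so the scan does not single out the tested motifs. Composition alone would raise the other orders too, yet only 1 of the 59, GGATAA, reached the lower bound of 1.66. By this later reading the values argue against composition as the source, although the criterion set in advance did not exclude it. The odds ratios also reflect the lower genes, whose share of 17.5% lay under the 22.4% of coding genes. As a hypothesis, part of the higher genes may respond through such elements, which rests on these shares and odds ratios alone, as binding was not tested.

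Calls in genes described by the words proteasome or ribosomal protein, which leaves out subunits such as RPN12b, were 57 higher against 3 lower. Those in genes with receptor anywhere in the description were 17 higher against 63 lower. The median transcript lengths of these called genes were 1234 and 2567 bases. Uncalled members of both sets were not counted. In the narrower keyword families of ribosomal protein and receptor-like genes, most members were uncalled (307 of 344 and 114 of 148). Direction did vary with length over all calls, with 53.5% higher in the shortest decile, 62.4% in the next and 42.0% in the longest. Within length deciles the odds ratio was 15.7 (4.86 to 50.8) for proteasome and ribosomal protein genes and 0.229 (0.131 to 0.398) for receptor genes. Within deciles of GC content it was 16.4 and 0.217, against 15.6 and 0.207 without strata, which argues against either bias as the whole source. GATAAG lay within 500 bp of 29.8% of the higher proteasome and ribosomal protein genes and of 29.6% of other higher genes (one-sided Fisher's exact p = 0.539), which does not decide whether such elements act there. Whether the contrast follows from DIV1 or from making much protein from a plasmid cannot be told apart here, as what the ev plasmid encodes is not stated.

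Several of the highest folds belong to transcripts known from pollen or seed. Of the 7 pollen transcripts seen among them, PGA4, AT5G07430 and DAF1 had estimated ev means under the floor, so that no size is given, and SKS13, VGD1, AT2G33160 and STP2 had log2 fold changes of 5.95 (SE 1.71), 5.08 (SE 1.31), 5.66 (SE 1.24) and 6.41 (SE 0.95) in the authors' deposited table. Of 25 other pollen transcripts, listed before they were looked up, 4 were called higher and 0 lower. They were VGDH1 at 4.83 (SE 1.63) and AT3G07850 at 6.40 (SE 1.72) on the log2 scale, PGA3 with an ev mean under the floor, and TUA1, which at 0.45 (SE 0.16) is not among the high folds and was well detected in the ev libraries, in the authors' deposited table. The estimated ev mean of AT3G07850 was 0.98, close to the floor. VGDH1 lies close to the seen VGD1 on chromosome 2, and PGA3 close to AT3G07850 on chromosome 3. Reads shared between these copies were not examined. Of 11 other seed transcripts 0 were called, CRU2 being the seen one. The criterion set in advance for pollen or seed RNA as the source was at least as many listed members called higher as not. Neither list met it. The criterion against such a source, a listed member called lower, was not met either, and it had little room to be met. No called gene had a mean under 20.4, so a transcript near the floor in the ev libraries could hardly be called lower. That criterion therefore decides nothing. Pollen RNA or seed RNA in div1 libraries may still be the source, or activation of these genes, since a table of called genes does not show the level of the rest. With no values per library, a single library could carry these folds, which was not testable.

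DIV1 had the largest standard error, 0.884, of 221 called genes with a mean of at least 10000, whose median was 0.156 and next largest 0.487. Under a negative binomial model with 4 against 4 libraries this corresponds to a coefficient of variation of 86.6%, against a median of 15.3%. A gene with a large standard error is called only if its fold change is large, so both medians are low by selection. How unusual the spread of DIV1 is among all genes cannot be told. Because ACX1 had the smallest adjusted p, 25 genes of peroxisomal fatty acid breakdown were examined. Of these 5 were higher, ACX1 itself and PED1 at 1.61 (SE 0.12) among them, and 2 lower, in the authors' deposited table. The one-sided hypergeometric p of 0.0722 is an upper bound only as regards untested members and counts the gene that prompted the test, so it decides nothing.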
